A study of Homo sapiens with 6 samples.

How the data were processed

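RNA of Caco-2 cells in 2 groups, vector control and FABP1 antisense, was sequenced in 3 libraries each. Per the labels' protocols, RNA was extracted with TRIzol, samples of high integrity were kept, and libraries were made with the TruSeq Stranded mRNA kit. The submitters' processing notes name bcl2fastq, Trimmomatic 0.38, HISAT2 2.1.0, Bowtie2 2.3.4.1 and StringTie 1.3.4d and the build GRCh37, without the role or order of each tool. Whether counting used the strand is not given in the sources used here, so a gene and an antisense partner could not be told apart.

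The deposited table held read counts per gene and library that the authors had not normalized, for 27685 genes by Entrez ID and symbol. These deposited counts were used throughout. The other 12 per-library columns, which per the file headers hold FPKM and TPM, were not used here. Columns could be matched to groups only, so 1 measure with as many columns as samples was kept, the counts. The numbers in the column headers were 2, 3 and 4, while the labels number the replicates 1, 2 and 3. Each column was therefore assigned to its group by the group name in the header, and libraries are named by header number.

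Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr (14640 kept), libraries scaled by TMM, and the groups compared with the quasi-likelihood test (glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values were computed on TMM effective library sizes, and means are given with the SD of 3 libraries. The standard error of a log2 fold change was approximated as its absolute value over the square root of the F statistic. The 95% intervals used the total degrees of freedom of the test, residual plus prior. For a gene with 0 counts in a group, the fold is a lower bound against 3 counts over that group. Such floors cover counting error only. Libraries of 1 group differed by more than counting noise (chi-square per degree of freedom 16.0 to 46.9), which does not show that they are separate cultures. Each library was taken as 1 replicate because the labels number them so. The biological coefficient of variation was 11.8%.

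Before the data were examined, 39 gene lists were fixed to suit an intestinal cell line and a fatty acid carrier, along with the designs, the alternatives and the rule for naming genes. Lists with at least 5 tested members (36) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. The list of mitochondrially encoded genes matched 0 symbols in the table, although the table held mitochondrial ribosomal RNAs under the symbols RNR1 and RNR2. The enteroendocrine and endothelial lists had 4 and 3 tested members. The rule named FABP1 and the 10 largest rises and 10 largest falls by fitted log2 fold change. These needed a mean log2 CPM of at least 1, adjusted p under 0.05 and no overlap of the groups. A fixed set of key genes was added, and up to 4 members per list with the largest changes at that level. Some genes that the rule selects are not reported here. Members outside the rule were named after their values were seen, mostly where 5 or fewer members of a list rose or fell.

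Gene order came from a RefSeq table of another build (GRCh38.p14), used without coordinates, which placed 14602 of the tested genes (99.7%). Running medians used genes with a mean log2 CPM of at least 3. GC content and transcript length came from GENCODE transcripts, matched by RefSeq accession. The analysis of gene order was chosen after seeing the data. Alternatives covered scaling (DESeq2 1.42.0 size factors, library size only), filters, tests (DESeq2, glmTreat), leaving out each library, and a block on the header numbers. A limma test on log2(TPM + 1), listed before the data were seen, was run and then withdrawn with the columns it needed. The length test had first used lengths derived from FPKM and was run again with reference lengths. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

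The test was tried on simulated data drawn from the means, library sizes and dispersions of the 14640 tested genes of this comparison, with 200 genes changed. It recovered 70.1% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, with 11 false calls among 14440 unchanged genes. With no changed gene it made 1 call. In a run with a list of 30 genes raised 1.5-fold, camera called 0 of 40 unchanged lists. Genes were drawn independently, so the false calls of lists with correlated members were not measured. Far fewer genes were changed here than the 55.0% called in the data, so these rates need not carry over.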

Results

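Caco-2 is an established human colorectal cancer cell line whose cells take on features of intestinal absorptive cells (enterocytes). The series measured polyA RNA of these cells by RNA sequencing. It set cells mock-transfected with the empty vector pcDNA3 against cells carrying a construct antisense to FABP1, the gene of a cytosolic carrier of long-chain fatty acids in liver and intestine, and asked how gene expression differed. Each group had 3 libraries. Total counts were 57979037, 40351394 and 43673999 in vector control libraries 2, 3 and 4, and 41768687, 44496791 and 55153051 in FABP1 antisense libraries 2, 3 and 4, by the numbers in the column headers. At this depth 3 counts over a whole group corresponded to 0.0212 CPM (counts scaled to a common library size) in the vector control and 0.0211 CPM in the other group.

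FABP1 (gene ID 2168) was not lower in the libraries labelled FABP1 antisense. Its level was 138, 102 and 121 CPM in the vector control libraries (mean 120 ± 18.0, SD, n = 3) and 134, 147 and 122 CPM in the libraries labelled FABP1 antisense (134 ± 12.4, SD, n = 3). The log2 fold change was 0.16 (SE 0.12, 95% interval -0.10 to 0.42), and the groups overlapped. It did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.268). The second group is therefore named by its label alone, and every rise or fall reported here is that of the libraries labelled FABP1 antisense relative to the vector control. The table gave 1 total per gene without strand, so RNA of the construct and of the gene itself could not be separated. Among other fatty acid binding proteins, FABP2 had 0 counts in the vector control group and 10 in the other, FABP3 had 5 and 16, and FABP5 had 0 and 33, too few to be tested.

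Of all tested genes 55.0% differed between the groups, and intestinal and lipid-handling genes were among them. MTTP, which loads lipid onto apolipoprotein B, rose from 0.0674 ± 0.0584 to 57.3 ± 4.57 CPM (SD, n = 3 per group), and the brush border disaccharidase gene SI rose from 0.255 ± 0.141 to 22.3 ± 2.46 CPM. In the other direction, the apolipoprotein genes APOB and APOA4 went from 720 ± 123 to 203 ± 10.7 CPM and from 30.8 ± 2.62 to 0.866 ± 0.0749 CPM. DKK1, a secreted inhibitor of Wnt signalling, fell by 3.16 on the log2 scale from 1459 ± 71.5 CPM. All 3 libraries of one group lay beyond all 3 of the other for each of these 5 genes.

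**Figure D1:**
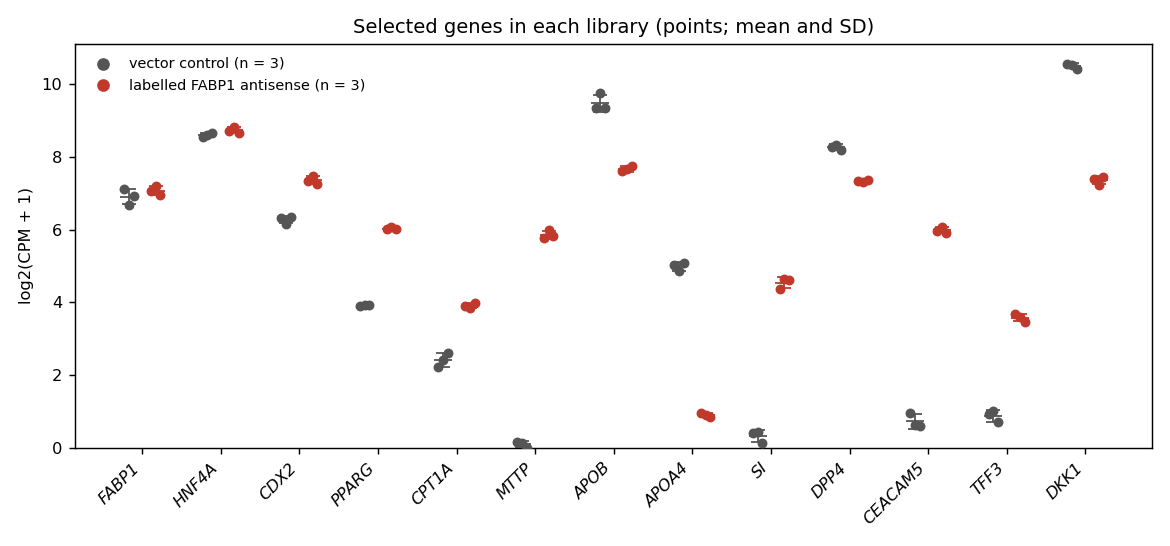
Level of 13 selected genes in each library, as log2(CPM + 1), with vector control libraries in grey and libraries labelled FABP1 antisense in red; points are libraries, and bars give the mean and SD of 3. FABP1 overlapped between the groups, while MTTP and SI lay higher and APOB, APOA4 and DKK1 lower in all 3 libraries labelled FABP1 antisense.

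Counts of list members were the same adjusted over the list alone unless given. Of 14640 genes tested, 4062 were higher and 3992 lower at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), or 55.0% in all. At least a 2-fold change was found in 2185 of these, 1289 higher and 896 lower, and at least an 8-fold change in 410 and 148. The groups did not overlap in 9174 genes (62.7%), against 10% by chance for 3 against 3. Correlations of log2 CPM between libraries were 0.984 to 0.989 within a group and 0.921 to 0.927 between groups. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The labels do not say how many transfected lines or clones each group came from, so a difference between lines cannot be separated from an effect of the antisense construct.

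**Figure D2:**
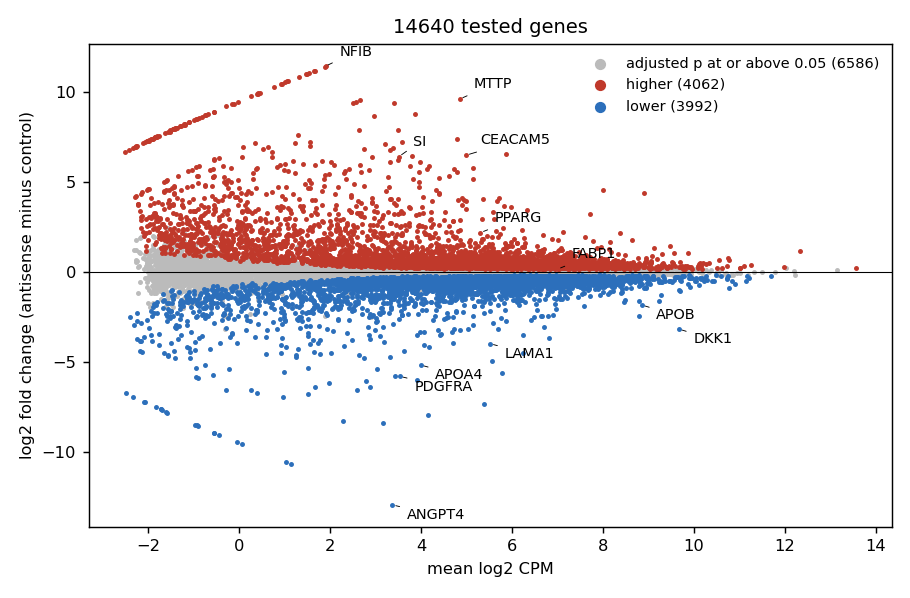
Log2 fold change (libraries labelled FABP1 antisense minus vector control) against mean log2 CPM for the 14640 tested genes, with genes that passed the test in red (4062 higher) and blue (3992 lower). The straight lines of points at the upper and lower left are genes with 0 counts in one group, whose fitted fold change is no estimate of size.

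The 10 largest rises by fitted fold change were of genes with 0 counts in the vector control group. Their fold is given as a lower bound against 3 counts over that group, and their rank is no estimate of size. MTTP, 782-fold higher from 10 counts over the vector control group, lay above all of these bounds. PPP1R1B, a protein phosphatase inhibitor regulated by cyclic AMP, was at least 348-fold higher at 7.43 ± 0.434 CPM, and the transcription factor gene NFIB at least 346-fold higher at 7.25 ± 0.923 CPM (SD, n = 3). MSR1, a macrophage scavenger receptor, was at least 294-fold higher, the tetraspanin CD82 at least 286-fold and ANKRD22 at least 273-fold. ANXA13, an annexin of intestinal epithelium, and CEACAM7, a surface glycoprotein of differentiated colon cells, were at least 259-fold and 256-fold higher. The actin-severing protein gene SCIN, EYA4 and the folate enzyme gene ALDH1L1 were at least 227-fold, 196-fold and 191-fold higher. In total, 30 genes had 0 counts in the vector control and at least 1 CPM in the other group, and 9 genes had the reverse.

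Among the 10 largest falls by fitted fold change, 3 genes had 0 counts in the libraries labelled FABP1 antisense. The rank of these 3 genes is likewise no estimate of size. The angiopoietin gene ANGPT4, at 20.6 ± 1.26 CPM in the vector control (SD, n = 3), was at least 967-fold lower, CPN2 at least 204-fold and LOC110384692 at least 191-fold. The sialidase gene NEU4 changed by -8.40 on the log2 scale (SE 0.50) and ANKRD65 by -8.27 (SE 0.48). SPX, which encodes a secreted peptide, had a log2 fold change of -7.93 (SE 0.22), and TMEM52B one of -7.35 (SE 0.16) from 83.1 ± 8.41 to 0.517 ± 0.122 CPM. WNT6, SOHLH1 and the acute phase gene ORM1 stood at -6.75, -6.41 and -6.52. ORM1 has a near-identical neighbour, ORM2, so reads could be split between them and its value is uncertain.

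Genes of fatty acid oxidation rose more often than they fell. In the list of fatty acid oxidation and ketogenesis, 12 of 29 tested genes rose and 6 fell, or 12 and 7 adjusted over the list alone. CPT1A, the gate of fatty acid entry into mitochondria, rose by 1.68 (SE 0.13) and ACAA2, a thiolase, by 0.88. Members of small groups that are named although the naming rule left them out were chosen after their values were seen. Of 12 fatty acid uptake and activation genes, ACSL1 (2.59), ACSM3 (2.02), ACSS1 (0.75), ACSL4 (0.45) and SLC27A5 rose, and SLC27A3 (-0.96), SLC27A2 (-0.55), SLC27A4 (-0.45) and ACSL5 (-0.23) fell. In the list of fatty acid binding proteins, FABP6, the ileal bile acid carrier, was at least 39.8-fold higher from 0 counts, RBP2 (0.84), CRABP1 (0.51) and DBI (0.50) rose, CRABP2 fell by 2.96, and 3 of 8, FABP1 among them, did not pass. Neither these lists nor the PPAR target list stood apart from other genes by camera with Benjamini-Hochberg adjustment (adjusted p = 0.560, 0.707, 0.319 and 0.479).

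The PPAR nuclear receptors, which are activated by fatty acids, moved in different directions. PPARG rose from 14.1 ± 0.149 to 64.5 ± 1.74 CPM (log2 fold change 2.19, SE 0.07) and PPARA from 22.5 ± 1.65 to 29.8 ± 1.61 CPM (0.41, SE 0.08), while PPARD went from 24.4 ± 2.51 to 13.6 ± 1.16 CPM (-0.85, SE 0.10; SD, n = 3). PPARD lay at the end of a stretch of the gene order, from TCF19 to PPARD, where most genes were lower (median -0.35). Of 26 PPAR target genes, 11 rose, 9 fell and 6 did not pass. CREB3L3 rose by 2.18, and the desaturase gene FADS2 fell by 2.46. ANGPTL4 and PLIN2, both widely used PPAR targets, did not pass (0.56, SE 0.36, and 0.08, SE 0.08).

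Fatty acid synthesis genes fell more often than they rose. Of 18 tested, 8 fell, including FASN (-0.69, SE 0.10), SCD5 (-1.41), the mitochondrial citrate carrier SLC25A1 (-0.89) and ME1 (-0.80). FASN and SLC25A1 had no running median along the gene order, so a shift shared with neighbours was not assessed for them. MLXIPL (0.70), ELOVL7 (0.63), ACACB (0.59) and ELOVL6 (0.37) rose, and SCD (-0.04, SE 0.06) did not pass. Of 25 genes of cholesterol synthesis and uptake, 8 fell, TM7SF2 (-0.83) among them, and 4 rose, including INSIG1 (2.59) and NSDHL (0.29). Of these 8 falls, 5 lay in shifted stretches of the gene order, and outside such stretches 3 genes rose and 3 fell. The regulator SREBF2 fell by 0.43 (SE 0.08) and SREBF1 did not pass (-0.11, SE 0.11). SREBF2 lay in a shifted stretch, from SNU13 to SMDT1, with a median of -0.47, so its fall was no larger than that of its neighbours. Of 25 genes of triglyceride synthesis and lipid droplets, 7 rose and 8 fell, or 9 and 8 adjusted over the list alone; outside shifted stretches 7 rose and 5 fell. The monoglyceride lipase gene MGLL went from 1.90 ± 0.566 to 68.9 ± 3.35 CPM (SD, n = 3), and CIDEC, GPAT3 and MOGAT3 rose by 2.13, 1.71 and 1.22. None of these 3 lists stood apart from other genes by camera with Benjamini-Hochberg adjustment (adjusted p = 0.317, 0.984 and 0.811), and for cholesterol the median and mean were positive while the test pointed down.

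Of 17 tested lipoprotein assembly genes, 9 fell, 4 rose and 4 did not pass. APOH, APOC3 and APOB fell by 2.62, 2.57 and 1.82 on the log2 scale (SE 0.11, 0.10 and 0.12) and APOA4 by 5.16 (SE 0.12), while MTTP rose by 9.61 (SE 0.27), from 10 counts over the vector control group. PLTP (0.88), APOM (0.62) and SAR1B (0.37) also rose, and APOA1 did not pass (0.15, SE 0.13). The list did not stand apart from other genes by camera with Benjamini-Hochberg adjustment (adjusted p = 0.261). It passed downward without genes in shifted stretches of the gene order (adjusted p = 0.0492 by camera), a fit chosen after seeing the data. The stretches were defined by the same fold changes, so this call is no independent evidence of a fall. In that fit 8 of 14 genes fell and 2 rose.

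Enterocyte genes rose more often than they fell. Of 33 tested genes of enterocyte differentiation, 19 rose and 9 fell, over all genes and adjusted over the list alone, with a median log2 fold change of 1.46. CEACAM5, an adhesion glycoprotein, rose from 0.669 ± 0.248 to 62.5 ± 3.79 CPM, and the chloride-bicarbonate exchanger gene SLC26A3 from 0.170 ± 0.0654 to 14.9 ± 0.665 CPM (SD, n = 3). CDX2, a transcription factor of intestinal identity, rose by 1.09 (SE 0.08) and ALPI, the intestinal alkaline phosphatase gene, by 0.45 (SE 0.10). The largest falls were of the glucose transporter gene SLC2A2 (-1.77) and CUBN (-1.66), named after their values were seen. The peptidase gene DPP4 fell by 0.93 (SE 0.07) from 309 ± 15.9 CPM, and VIL1, the microvillus protein villin, by 0.20 (SE 0.07), a call lost in 5 of 6 fits that left out 1 library. HNF4A did not pass (0.13, SE 0.07). The list stood apart from other genes by camera with a preset correlation and Benjamini-Hochberg adjustment (adjusted p = 0.0158). That call was lost with an estimated correlation (adjusted p = 0.802 with an estimated correlation) and without genes in shifted stretches of the gene order (adjusted p = 0.0693 by camera). Without those stretches 15 of 27 genes still rose and 9 fell, with a median of 1.07.

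Secretory cell genes rose from low levels. Of 14 tested goblet and secretory genes, 10 rose and 1 fell, over all genes and adjusted over the list alone, with a median log2 fold change of 2.56. FCGBP, a mucus protein, rose by 3.72 (SE 0.30) to 8.09 ± 1.43 CPM, the trefoil peptide genes TFF3 and TFF1 by 3.69 and 3.09, and KLK1 by 2.63 (SD, n = 3). ITLN1 fell by 1.80. The list stood apart by camera with Benjamini-Hochberg adjustment (adjusted p = 0.000900), a call lost with an estimated correlation (adjusted p = 0.802 with an estimated correlation). Markers of other cell types moved both ways: among 8 fibroblast and stromal markers LUM (7.12), DES (2.65), S100A4 (2.56) and COL3A1 (0.69) rose and PDGFRA (-5.78), PDGFRB (-1.13) and FBLN1 (-0.96) fell. Among 6 leukocyte markers CSF1R (3.60), LYZ (1.04) and CD68 (0.69) rose and CD14 fell by 2.38. Of 5 tested Paneth cell genes, MMP7 (5.11), REG1A (3.53) and LYZ rose and PLA2G2A fell by 2.13. These 3 lists did not stand apart by camera with Benjamini-Hochberg adjustment (adjusted p = 0.811, 0.466 and 0.578).

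Epithelial junction and keratin genes also rose. Of 35 tested, 22 rose and 4 fell, or 23 and 4 adjusted over the list alone, with a median of 0.31. KRT20, a keratin of mature intestinal epithelium, rose by 3.17 (SE 0.20), the claudin genes CLDN3 and CLDN4 by 1.97 and 1.35, and CDH17, an intestinal cadherin, by 1.32 from 320 ± 21.2 to 797 ± 17.5 CPM (SD, n = 3). CDH1 rose by 0.20 (SE 0.06), a call lost in 4 of 6 fits that left out 1 library. The falls were of F11R (-0.59), RAB25 (-0.55), KRT19 (-0.51) and CLDN2 (-0.37). The list stood apart by camera with Benjamini-Hochberg adjustment (adjusted p = 0.0158), a call lost with an estimated correlation (adjusted p = 0.802 with an estimated correlation).

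Nuclear genes of the mitochondrial respiratory chain rose by small amounts. Of 37 tested, 25 rose and 2 fell, or 26 and 2 adjusted over the list alone, with a median of 0.41. The cytochrome c oxidase subunit genes COX6A1, COX7B and COX6C rose by 0.99, 0.81 and 0.70 (SE 0.09, 0.08 and 0.10). ATP5G1, for a subunit of ATP synthase, fell by 1.12. The list stood apart by camera with Benjamini-Hochberg adjustment (adjusted p = 0.000900), a call lost with an estimated correlation (adjusted p = 0.802 with an estimated correlation). The share of counts from RNR2, a mitochondrial ribosomal RNA, was 0.292, 0.339 and 0.308% in the vector control libraries and 0.745, 0.701 and 0.726% in the libraries labelled FABP1 antisense. For RNR1, the other mitochondrial ribosomal RNA, the shares were 0.0823 to 0.0988% and 0.0914 to 0.115%.

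Wnt target and cell cycle genes did not move one way. Of 23 intestinal stem cell and Wnt target genes, 10 rose and 11 fell, or 10 and 12 adjusted over the list alone. DKK1 and SP5, both induced by Wnt signalling, fell by 3.16 and 3.17, while SMOC2 and LEF1 rose by 5.99 and 3.33, and the stem cell gene LGR5 did not pass (-0.19, SE 0.08). MYC rose by 0.51 (SE 0.06). Of 41 genes of the G1/S transition and DNA replication, 17 fell and 8 rose, and of 42 G2/M genes, 14 fell and 7 rose. E2F2, E2F1, RPA2 and GINS1 fell by 0.80, 0.71, 0.70 and 0.51, and CDC20, TPX2, GTSE1 and KIF2C by 0.90, 0.86, 0.75 and 0.68. Of these 8 genes, 7 lay in stretches of the gene order where most genes were lower. GTSE1 had no running median along the gene order, so a shift shared with its neighbours was not assessed. Inside all shifted stretches, 5 of 9 G1/S genes fell and 3 rose, and 6 of 10 G2/M genes fell and 1 rose. In the fit without these stretches, 12 of 32 G1/S genes fell and 4 rose. For G2/M, 8 of 32 fell and 6 rose in that fit, so falls and rises were closer in number there. MKI67, a proliferation marker, did not pass (-0.10, SE 0.09), and CDKN1A, a cell cycle inhibitor, rose by 0.35 (SE 0.09), a call lost in 2 of 6 fits that left out 1 library. These 3 lists did not stand apart by camera with Benjamini-Hochberg adjustment (adjusted p = 0.479, 0.281 and 0.319).

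**Figure D3:**
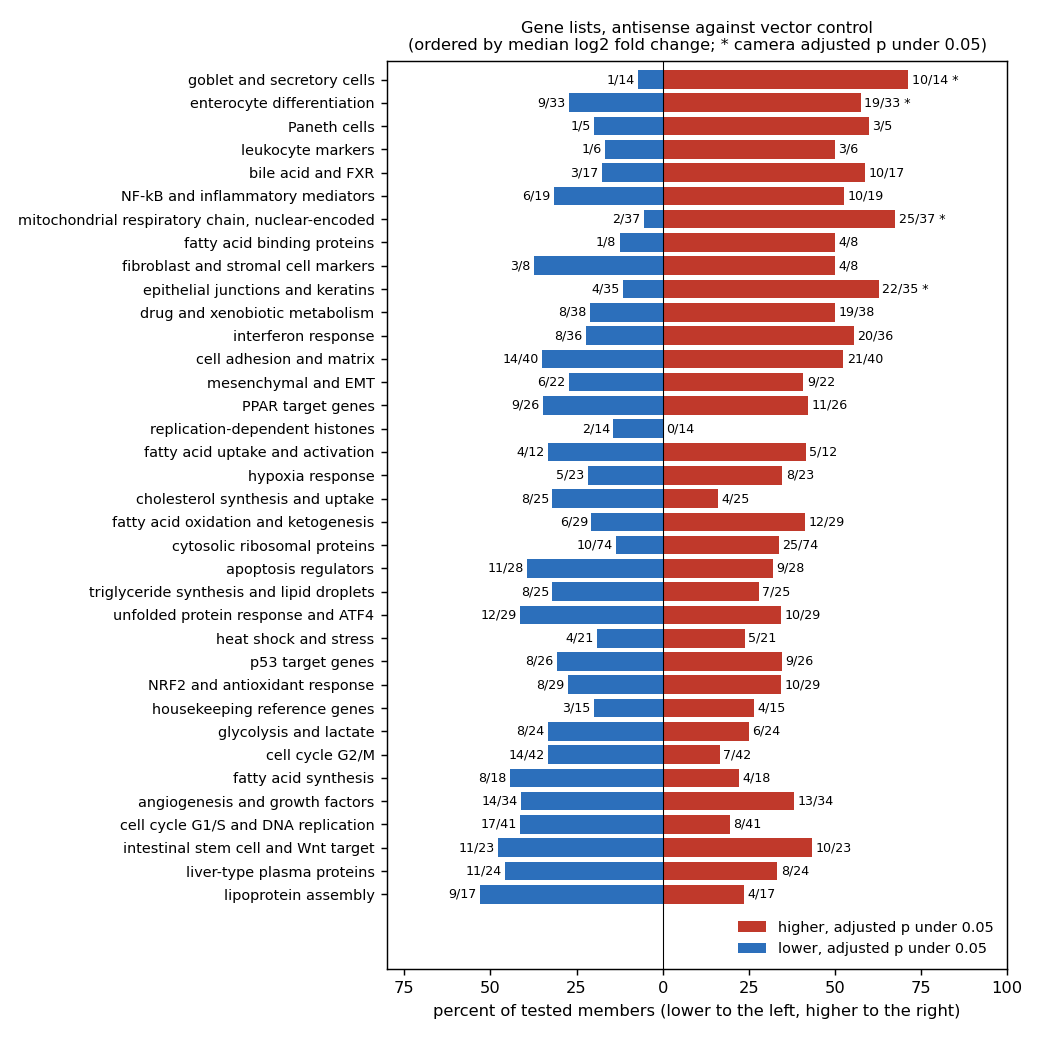
Percent of tested members of each of 36 gene lists that were higher (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05, with the counts beside the bars. Lists are ordered by median log2 fold change; the 4 marked with an asterisk passed camera at a preset correlation, and 0 passed with an estimated correlation.

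Fold changes were also shifted along the order of genes on the chromosomes. Running medians were taken over a gene and the 50 neighbours on either side, among 10015 genes. The 50 genes at either end of a chromosome had none and counted as outside shifted stretches. The largest absolute value was 0.59, against at most 0.28 in 1000 shuffled orders, and 24.8% of windows lay beyond that. The longest stretches ran from RPL22 to TOMM40L (median -0.44) and from EMG1 to DENR (0.42). Others ran from C5orf42 to KIF3A (0.34), CDC26 to LINC00094 (-0.39) and ENTPD6 to VAPB (-0.42). Stretches of this kind held 2745 genes. Of the named genes, CRABP2 and PLA2G2A fell inside the first, as did most genes there, while S100A4 rose inside it. LUM, LYZ and COX6A1 rose inside the stretch from EMG1 to DENR, where SPX and TMEM52B fell.

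**Figure D4:**
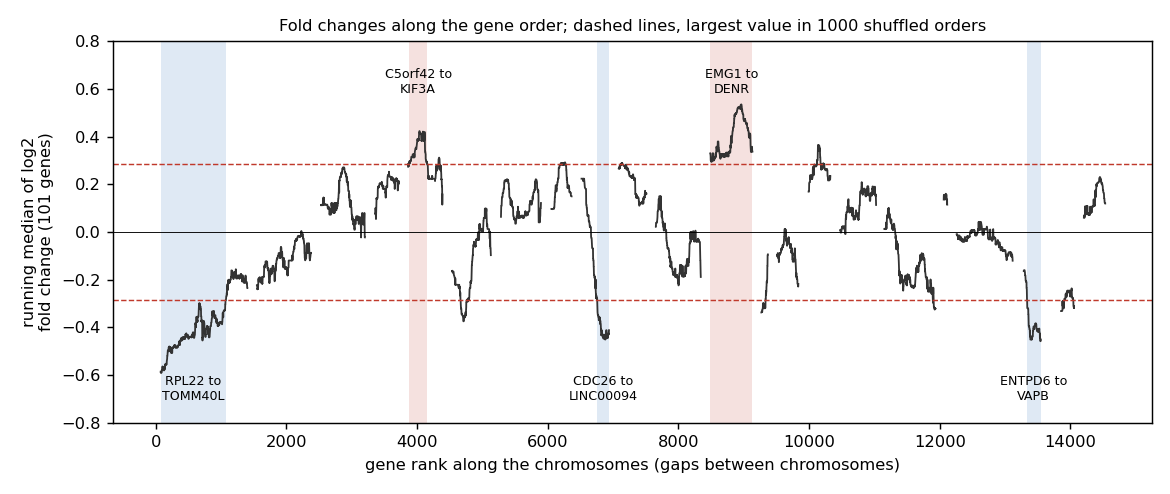
Running median of log2 fold change (libraries labelled FABP1 antisense minus vector control) over a gene and the 50 neighbours on either side, against gene rank along the chromosomes; dashed lines mark the largest value of 1000 shuffled orders, and shaded bands the 5 stretches of at least 75 windows beyond it. Medians reached -0.59 in the stretch from RPL22 to TOMM40L and 0.54 in that from EMG1 to DENR.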

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

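The block on header numbers and the fit without genes in shifted stretches were chosen after seeing the data. The stretches themselves were defined by the fold changes tested here. Of 14640 genes, 8054 passed, 2185 of them with at least a 2-fold change, and 5155 passed glmTreat against a 1.2-fold change, both stricter by construction. The other settings gave 5787 to 8103 genes, and 6983 to 8059 when 1 library was left out. In the settings reported, 0 genes were called in the opposite direction. FABP1 passed under no setting and stayed between 0.05 and 0.27 with 1 library left out. 4 lists passed camera, 4 to 5 with 1 library left out, 0 with an estimated correlation and 26 with fry, which does not compare a list with other genes. Without genes in shifted stretches, 6074 of 11895 genes passed. By camera with Benjamini-Hochberg adjustment, the call of enterocyte differentiation was lost there (adjusted p = 0.0693), though its median was still 1.07. Lipoprotein assembly passed downward by the same test (adjusted p = 0.0492, against 0.261 with all genes). Same-numbered libraries did not deviate together (residual correlations 0.03, -0.08 and -0.09). Paired samples without a shared deviation would look the same, so whether the header numbers pair the samples was not settled. A replicate block on the header numbers gave 6661 genes, a FABP1 value of 0.17 and 4 lists. One on the labels' numbers was not run because the columns do not carry them. A limma test on TPM was run, then withdrawn with the columns it needed; it had called a gene in the opposite direction and more falls than rises. Of 175 other genes named by the rule (members named outside it were not rerun), 7 changed their call or sign in at least 1 setting: VIL1, CDH1, VIM, CDKN1A and HIST1H2AC lost it, LGR5 gained it without vector control library 4 (-0.24) and SCD, which never passed, ranged from -0.0795 to 0.00606 with 1 library left out. The cause was not tested. Depth limits genes near 0.0212 CPM.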

Other observations

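The tests of a swap of libraries, of construct RNA, of depth, of fibroblast-like cells and of enterocyte maturity were chosen after the results they bear on were seen, as were the transcript lengths of the length test. Matrix and growth factor genes moved widely in both directions. Of 40 cell adhesion and matrix genes, 21 rose and 14 fell. The laminin gene LAMA1 fell from 85.9 ± 1.51 to 5.45 ± 0.822 CPM (SD, n = 3) and the matrix phosphoprotein gene SPP1 fell by 3.91, while CEACAM6 and ITGB8 rose by 3.96 and 3.93. Of 34 angiogenesis and growth factor genes, 13 rose and 14 fell, among them the growth factor receptor PDGFRA (-5.78), IGFBP7 (-3.18) and NRP1 (-2.34), with IGFBP2 higher by 5.57. In the mesenchymal list 9 of 22 genes rose and 6 fell, with THBS1 at -3.67, CYR61 at -1.27, TGFBI at -0.88 and SNAI1 at 0.92; the mean was -1.98e-06 and the median 0.20. Of 38 drug metabolism genes, 19 rose and 8 fell, or 19 and 10 adjusted over the list alone. The xenobiotic exporter genes ABCG2 and ABCB1 changed by 1.96 and -1.31, and CYP2J2 and UGT2A3 by 4.76 and -2.43. Of 17 bile acid genes, 10 rose, including the nuclear receptor gene NR0B2 (3.03) and the transporter gene SLC51B (1.77), and TTR (-1.49), BAAT (-0.76) and SLCO2B1 (-0.57) fell. Of 24 liver-type plasma protein genes, 8 rose and 11 fell, FGB among the rises, with ITIH2 at -2.14 and F10 at -1.63. None of these lists stood apart by camera with Benjamini-Hochberg adjustment (adjusted p = 0.528, 0.811, 0.808, 0.317, 0.113 and 0.350).

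Stress and immune lists were mixed. Of 36 interferon response genes, 20 rose, including GBP2 (2.67), GBP1 (2.42), OAS1 (1.88) and IFIT3 (1.61), and 8 fell, or 20 and 9 adjusted over the list alone. This list missed camera's threshold (adjusted p = 0.0739 with Benjamini-Hochberg adjustment) and passed it without a filter, with a stricter filter, and without vector control library 2 or 4 or antisense library 4, but not with an estimated correlation (adjusted p = 0.802 with an estimated correlation). Of 19 inflammatory mediators, 10 rose and 6 fell, with BIRC3 at 2.65, CXCL3 at 1.72 and CX3CL1 at -1.01. In the glycolysis list 6 of 24 rose and 8 fell, with ENO2 at -2.34 and the glucose transporter gene SLC2A3 at -1.60. Of 23 hypoxia genes 8 rose, NDRG1 by 1.48, and CA9 (-3.88), ADM (-1.51), PDK1 (-0.62), AK4 (-0.62) and SLC2A1 (-0.41) fell. For p53 targets the counts were 9 and 8 of 26, with GDF15 at 2.13 and PHLDA3 at -1.61, or 9 and 9 adjusted over the list alone. Apoptosis regulators gave 9 and 11 of 28, with BCL2 at -2.65, or 10 and 11 adjusted over the list alone. The unfolded protein response list gave 10 and 12 of 29, with VLDLR at -2.36 and SLC7A11 at 1.29, or 12 and 12 adjusted over the list alone. Of 29 antioxidant genes 10 rose and 8 fell, with GPX2 at 2.17 and FTH1 at 1.07. Of 74 ribosomal protein genes 25 rose and 10 fell, or 22 and 9 adjusted over the list alone, with RPS29 at 0.56. Of 21 heat shock and stress genes HSPB1 (1.09), JUNB (0.49), IER3 (0.39), IER2 (0.35) and EGR1 (0.30) rose and JUN (-0.43), HSPH1 (-0.30), HSPA8 (-0.22) and HSPD1 (-0.20) fell. Among 14 histone genes HIST1H2AC (-0.50, a call lost in 3 of 6 fits that left out 1 library) and HIST1H2BK (-0.46) fell, and among 15 housekeeping genes B2M (1.13), RPLP0 (0.41), PPIA (0.24) and PGK1 (0.18) rose and 3 fell, TBP (-0.47) and TFRC (-0.36) among them. Adjusted over the list alone, 0 histone genes rose and 1 fell, and 3 housekeeping genes rose and 3 fell. The lists too small to test held NTS (4.68), SCG5 (2.04) and CHGB (0.84), and VWF (2.85), PECAM1 (1.01) and ESAM (0.64), all higher. The median, mean and test differed in sign for the apoptosis, unfolded protein, antioxidant, histone and housekeeping lists. Apart from the interferon list, none came near camera's threshold with Benjamini-Hochberg adjustment (lowest adjusted p = 0.453, for inflammatory mediators).

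FABP1 was not lower in the libraries labelled FABP1 antisense. A swap of 1 or 2 libraries between the groups was excluded, since the lowest correlation within a group exceeded the highest between groups by 0.0577. RNA of the antisense construct counted as FABP1 cannot be told apart from the gene's own RNA, because the table holds 1 total per gene (log2 fold change 0.16). The running median of neighbouring genes at FABP1 was -0.11. Loss of the antisense effect in culture, or an effect on protein alone, may also account for it and was not tested.

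Genes seen in 1 group only (at most 3 counts against at least 1 CPM) numbered 58 with a place in the gene order, 45 of them in the libraries labelled FABP1 antisense. A difference in depth was excluded, with a ratio of summed counts of 0.996. For 0% of these genes did the median of the 10 nearest expressed genes shift by more than 1 in the same direction. These neighbours left out genes seen in 1 group only, so genes lost together would not have counted. Loss of whole chromosome segments was therefore not excluded for genes seen in 1 group only. Fibroblast-like cells in the cultures were excluded as the source of such genes: their abundant collagen genes COL1A1 (-0.05) and COL3A1 (0.69), with a median of 0.32, stayed far below LUM (7.12), and COL1A2 and DCN had 0 counts in all 6 libraries. Without the filter on low counts the stromal list had a median of 2.60, as it then held 4 more genes, with 0 counts in the vector control and 2 to 13 in the other group. A difference between the cells of the 2 groups that was present apart from the antisense construct may account for these genes and stays open.

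Shifts along the gene order are consistent with a hypothesis of different chromosome dosage in the 2 groups, whose largest running median of 0.59 exceeded all 1000 shuffled orders. GC content of transcripts was excluded as the whole cause, since the largest value after removing its trend was 0.503 against at most 0.276 in shuffled orders. That test used the largest value only, so it does not cover each stretch. After removal, the median from C5orf42 to KIF3A was 0.23, against 0.34 before. The other named stretches had medians of -0.42 (RPL22 to TOMM40L), -0.32 (CDC26 to LINC00094), 0.40 (EMG1 to DENR) and -0.39 (ENTPD6 to VAPB). DNA copy number was not analysed here, and shared regulation of neighbouring genes stays open.

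Of 10 splits of the 6 libraries into 3 and 3, 1 called as many as 8054 genes (highest other 0). The splits are too few to give a share under 0.05. For lists, 3 of the 10 splits called at least as many as 4 (highest other 5). The number of lists called by camera therefore did not set the real groups apart from mixed ones. A more advanced enterocyte differentiation or a higher culture density may account for part of the enterocyte rises and stays open. In the enterocyte and lipoprotein lists 6 genes with a mean log2 CPM of at least 1 fell by more than 1, SLC2A2 of the enterocyte list and APOA4, APOB, APOC3, APOH and LCAT of the lipoprotein list, but this count was taken from the pattern that prompted it and excludes nothing. A reading bias toward short transcripts was tested for the respiratory chain list and excluded, since its median of 0.41 lay at percentile 100 of 10000 random lists matched on length and level (central 95% from -0.13 to 0.15).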
